A study of Mus musculus with 6 samples.

How the data were processed

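RNA was measured by sequencing in 6 libraries of mouse blood platelets, 3 from wild-type mice and 3 from mice homozygous for the R734C change in integrin β3. Group and replicate number were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and a miRNeasy Micro kit, full-length cDNA was made with SMART-Seq HT, and libraries were made with Nextera XT. These kits do not mark the strand of the RNA, so fragments from exons that overlap a gene on the other strand cannot be told apart. The labels do not say whether the replicates of a group came from separate animals. P-values therefore measure the spread between these samples, which may be technical.

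The deposited values are FPKM per gene symbol (fragments relative to transcript length and to the fragments of the library), 1 table per library, with 24346 symbols in the same order in each. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1, with genome build mm10. Their settings and the gene annotation were not given in the sources used here. An exact 0 in such a table can be a failed estimate, so a value of 0 is reported only as listed at 0. Read counts were not analysed here.

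Depth was therefore assessed from the low values. The commonest ratio of low values between libraries gave the worth of 1 fragment and so the depth relative to wild-type library 1. It was 1.06 and 1.02 for wild-type libraries 2 and 3, and 0.882, 1.00 and 1.06 for knock-in libraries 1, 2 and 3. A rough absolute estimate from genes with 1 annotated transcript gave 8710000, 9280000 and 8980000 fragments for the wild type and 7830000, 8690000 and 9320000 for the knock-in. That estimate kept only genes whose implied fragment total lay within a window, 34 to 51 genes per library. The window was set after the values were seen and confines the estimate, so the absolute depth is uncertain. Median-of-ratios factors of the deposited values lay between 1.01 and 1.02. Factors from the total without erythroid and the most abundant genes separated the groups, at 0.965 to 0.980 in the wild type and 0.998 to 1.04 in the knock-in. Total FPKM was 641278 to 708432 in wild-type and 758381 to 856863 in knock-in libraries. As planned, the libraries were used without further scaling, and other scalings were tried as alternatives. Replicates shared no identical value above 0, and each was counted as a sample.

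Genes with a mean FPKM of at least 1 over the 6 samples were tested, 4859 of the 12260 symbols above 0 in any library. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, empirical Bayes with a variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p of 0.05. Log2 fold changes, their standard errors (SE) and folds are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Separately, genes whose group means of FPKM + 1 differed at least 2-fold were counted, because the series' design text names that limit. A comparison of 1 value between 3 and 3 samples cannot reach a two-sided exact p below 0.1, so single genes were judged by limma's adjusted p.

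A set of 23 gene lists was fixed before the data were examined. They cover platelet adhesion receptors, integrin activation and adhesion complexes, the RhoA pathway, Rac and Cdc42 signalling with actin filaments, tubulins and microtubules, alpha granules, and dense granules with the secretion machinery. They also cover G protein-coupled and cyclic nucleotide signalling, ITAM and tyrosine kinase signalling, inherited macrothrombocytopenia, and apoptosis with platelet life span. General lists were cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, the unfolded protein response, interferon-stimulated genes, and immediate early with heat shock genes. The remaining lists were cell division genes and markers of erythroid cells, neutrophils, monocytes and macrophages, T and NK cells, and B cells, and 1 list that, like some single genes, is not reported here but stays in the tests and counts. Lists with at least 5 tested members, 17 in all, were tested with camera in limma with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 17 lists. Camera was repeated with an estimated correlation. The repeat can give a much larger adjusted p even where the correlation hardly differs. For cytosolic ribosomal proteins the estimate was 0.0104, near the preset 0.01, while the camera adjusted p was 3.24e-15 with the preset and 0.0207 in the repeat. A call lost in the repeat is therefore not by itself a sign that list members vary together. Fry, also in limma, tests whether a list's genes move one way on balance, and its mixed form whether they change in either direction; neither compares a list with other genes.

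The rule for naming genes was also fixed before the data were examined. It took Itgb3 and Itga2b, then in each direction the 10 genes with the largest log2 fold change among those past the threshold with no overlap between the groups. Small RNAs and unnamed gene models were left out of that choice and kept in the tests. From each list it took the 2 tested members with the smallest unadjusted p and the member with the highest mean FPKM. Genes named outside the rule are described as chosen after their values were seen. Positions and transcript lengths came from GENCODE M21 on GRCm38, the assembly that mm10 names, and positions are those of whole protein-coding genes. Exons of 22 of the 79 named genes overlap those of another annotated gene, so their values are uncertain. Besides those pointed out with the results, they include Selp, P2ry1, Orai1, Pde5a, Tbxas1, Tpm4, Tuba1a, Rhoa, Uqcrb, Cd37, Tgm2 and Ctla2a.

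The limma step was tested on simulated data for 4859 genes, with the means of this comparison and spreads drawn around its trend with expression. It recovered 23.9% of 67 genes changed 1.5-fold, 55.2% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. Of 124 calls, 6 were false. With no changed gene it called 0 genes and 0 of 17 lists. Genes were drawn independently of each other. The result for lists therefore does not show how camera with the preset correlation behaves where list members vary together. Changes of 1.5-fold or less are thus mostly missed at this sample size.

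Alternatives planned beforehand were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, 3 other scalings, other variance models, sample weights, small RNAs left out, the replicate number as a block, each library left out in turn, and other set tests. Chosen after seeing the data were the joint omission of the 2 libraries richest in haemoglobin mRNA in their groups, and the removal of a trend with transcript length by loess, with and without the replicate block.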

Results

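Platelet RNA was sequenced from wild-type mice and from mice homozygous for R734C, a missense change in the cytoplasmic part of integrin β3. Integrin β3 pairs with αIIb to form the platelet fibrinogen receptor. The comparison asked which platelet mRNAs differ between the genotypes, and the series title names large platelets in low number and the RhoA pathway. Each group had 3 libraries, with 9006, 8910 and 8600 genes above 0 FPKM in the wild type and 8998, 8773 and 8383 in the knock-in. Depth was roughly estimated at 7830000 to 9320000 fragments per library, by a method whose window confines the estimate. Pearson correlations of log2 values across genes were 0.973 to 0.981 within the wild type, 0.956 to 0.978 within the knock-in and 0.958 to 0.969 between the groups.

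Itgb3, the gene that carries the change, was 1.40-fold lower in knock-in platelets, at 859 ± 50.8 FPKM against 1208 ± 104 in the wild type (SD, n = 3 each). Its log2 fold change was -0.49 (SE 0.09, limma adjusted p = 0.0190), and it was lower in 3 of 3 knock-in libraries. Itgb3 lies on chromosome 11 at 104608000 to 104670476 of GRCm38, plus strand. Itga2b, which encodes the partner αIIb (chromosome 11, 102453297 to 102470122, minus strand), measured 4617 ± 277 FPKM in the wild type and 4240 ± 222 in the knock-in (SD, n = 3). That difference did not pass the test (log2 fold change -0.12, SE 0.08, limma adjusted p = 0.412). A missense change cannot be seen in an expression level, so neither gene checks the genotype labels. The Itgb3 call was lost without a filter on low values (adjusted p = 0.0740), without the variance trend (0.105) and after removal of a transcript length trend (-0.38, 0.0599). It was also lost without wild-type library 2 (0.0884) or 3 (0.0873) and without knock-in library 2 (0.0872) or 3 (0.0676).

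The genotypes differed in 406 of 4859 tested genes, 212 higher and 194 lower in the knock-in (limma, adjusted p under 0.05). All 406 had values that did not overlap between the groups. Over all tested genes 30.7% did not overlap, where chance gives 10%. The median absolute log2 fold change of the 406 genes was 0.74, and 82 of them were at least 2-fold apart by group mean. By that 2-fold limit alone 151 genes differed, 70 higher and 81 lower, of which 125 did not overlap and 69 had a mean FPKM under 5. That count depended on the setting: 381 genes (202 higher) with a pseudocount of 0.1, 32 (11 higher) with 5, 82 (33 higher) at a mean FPKM of at least 5, 297 (105 higher) without knock-in library 1, 245 (133 higher) without wild-type library 1, 352 (152 higher) without both libraries richest in haemoglobin mRNA in their groups, and 151 with 50 higher after rescaling without erythroid and top genes. Across 4826 genes, which are not independent replicates, the log2 fold change was lower for longer transcripts (Spearman correlation -0.196). Without knock-in library 3 no gene passed (994 at an unadjusted p under 0.05), and none passed in limma without the variance trend (1197). The count was 107 with no filter, 41 without wild-type library 2, 113 without wild-type library 3, 85 without knock-in library 2 and 610 without knock-in library 1.

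Among abundant mRNAs that rose, Pdzk1ip1, which encodes a small membrane protein, went from 348 ± 27.4 to 812 ± 76.8 FPKM (SD, n = 3), a 2.33-fold rise (limma adjusted p = 0.00759). Trf, encoding transferrin, had the largest rise, with a log2 fold change of 1.79 from 0.343 ± 0.385 to 3.79 ± 1.97 FPKM (SD, n = 3). Fabp4 and Fabp5, which encode fatty acid binding proteins, rose by 1.74 and 1.48 on the log2 scale. Mrpl42, for a mitochondrial ribosomal protein, rose by 1.56, from 3.77 ± 0.950 to 13.1 ± 2.77 FPKM (SD, n = 3). The RNA polymerase II subunit gene Polr2j rose by 1.57, Rpl36 by 1.49, Ly6c1 by 1.46, Hist1h2ak by 1.24 and Akip1 by 1.23. Of these 10 genes, Trf, Fabp4, Polr2j, Fabp5, Ly6c1, Hist1h2ak and Akip1 stayed under 10 FPKM in both group means.

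The largest fall was that of Rab32, a small GTPase of lysosome-related organelle transport, from 8.32 ± 3.08 to 0.815 ± 0.187 FPKM (SD, n = 3), with a log2 fold change of -2.30 (limma adjusted p = 0.00794). Gstt1, a glutathione S-transferase gene, fell from 95.1 ± 52.0 to 20.4 ± 1.44 FPKM (SD, n = 3), with wild-type values between 63.6 and 155. Thbs1, encoding thrombospondin-1 of the alpha granules, fell from 1294 ± 186 to 419 ± 116 FPKM (SD, n = 3), 3.15-fold (limma adjusted p = 0.00759). It lies on chromosome 2 at 118111876 to 118127133, plus strand. Other large falls on the log2 scale were -1.77 for the uridine-cytidine kinase-like gene Uckl1, -1.49 for the exoribonuclease gene Eri1 and -1.42 for Tcp11l1. Serpini1, encoding neuroserpin, had -1.42, the complex III assembly gene Uqcc1 -1.39 and the dihydropteridine reductase gene Qdpr -1.34. Exons of Thbs1, Uckl1, Qdpr, Polr2j, Akip1, Trf and Hist1h2ak overlap those of another annotated gene, and Ly6c1 and Hist1h2ak have near-identical copies, so their levels are less certain.

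**Figure D1:**
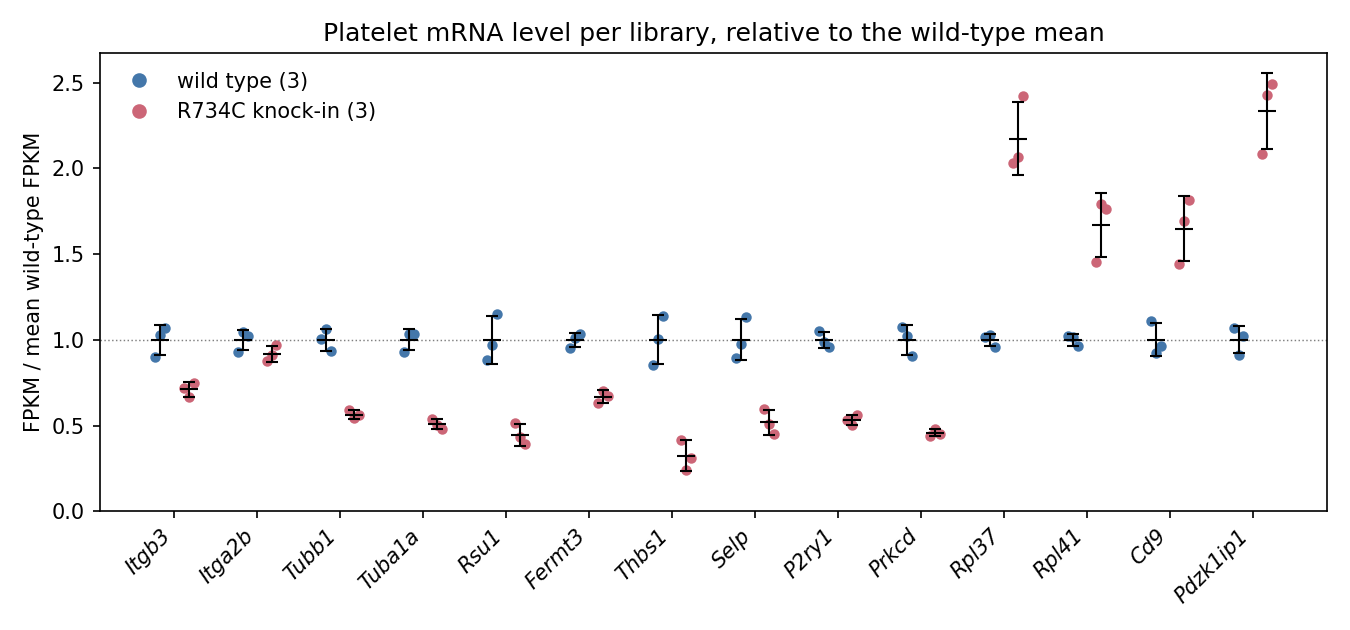
FPKM of 14 named genes in each library, divided by the wild-type mean of the gene (vertical axis, no unit). Points are the 3 wild-type (blue) and 3 knock-in (red) libraries, and bars show the mean ± SD; Itga2b overlaps between the groups, while the groups of the other genes are apart.

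Genes of the tubulins and microtubules list were lower in the knock-in. Of 19 tested members, 9 fell and 0 rose over all genes tested, 10 and 0 adjusted over the list alone, and the median log2 fold change was -0.43. The 9 falls became 3 with no filter, 3 without wild-type library 2, 5 without wild-type library 3, 3 without knock-in library 2 and 0 without knock-in library 3. Tubb1, the main β-tubulin of the platelet marginal band, fell from 6574 ± 414 to 3710 ± 174 FPKM (SD, n = 3), 1.77-fold (limma adjusted p = 0.00759; chromosome 2, 174450695 to 174457882, plus strand). Tuba1a, an α-tubulin gene with near-identical copies, fell from 234 ± 14.2 to 119 ± 6.81 FPKM (SD, n = 3). The list passed camera (adjusted p = 0.000166; adjusted p = 0.159 with an estimated correlation). The overlapping list of inherited macrothrombocytopenia genes had 5 members that fell and 0 that rose of 17, the same adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.00774; adjusted p = 0.268 with an estimated correlation). These were Tubb1, Gp1ba, Itgb3, the megakaryocyte transcription factor gene Gata1 and the tropomyosin gene Tpm4, the last chosen after its values were seen. Gata1 fell from 93.0 ± 1.10 to 59.3 ± 4.86 FPKM (SD, n = 3). The 5 falls became 2 with no filter, 1 without wild-type library 2 or 3 and 2 without knock-in library 2, with 1 rise and 6 falls without both libraries rich in haemoglobin.

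Integrin activation and adhesion complex genes were also lower. Of 25 tested, 7 fell and 0 rose, 9 and 0 adjusted over the list alone, with a median log2 fold change of -0.29 (camera adjusted p = 8.2e-05; adjusted p = 0.159 with an estimated correlation). Rsu1, a binding partner of the integrin-linked kinase complex, fell from 835 ± 115 to 372 ± 51.7 FPKM (SD, n = 3), 2.24-fold. Fermt3, which encodes the integrin activator kindlin-3, fell from 2339 ± 97.3 to 1564 ± 84.5 FPKM (SD, n = 3; log2 fold change -0.58, limma adjusted p = 0.00849). The adhesion protein gene Zyx had a log2 fold change of -0.32 that did not pass (limma adjusted p = 0.0726). Fermt3 and Zyx overlap exons of other genes on the opposite strand. The 7 falls became 4 after removal of the length trend, 2 with no filter, 1 without wild-type library 2, and 2 without wild-type library 3 or knock-in library 2.

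Of 19 adhesion receptor genes, 4 fell and 1 rose, 7 and 2 adjusted over the list alone, with a median of -0.21. Gp1ba, a subunit of the von Willebrand factor receptor, fell from 305 ± 41.0 to 192 ± 1.68 FPKM (SD, n = 3). Besides Itgb3, the others that fell, chosen after their values were seen, were the junctional adhesion molecule gene F11r (log2 fold change -0.83) and Pecam1 (-0.36). Cd9, a tetraspanin gene whose exons overlap a transcript on the other strand, rose from 15105 ± 1459 to 24902 ± 2873 FPKM (SD, n = 3; limma adjusted p = 0.0105). The list's camera adjusted p of 0.0448 became an adjusted p = 0.324 with an estimated correlation, 0.0516 with median-of-ratios scaling, 0.0815 at a mean FPKM of at least 5, 0.125 without the variance trend, 0.0534 with sample weights and 0.0746 after removal of the length trend. It was 0.0620 without wild-type library 2, 0.0897 without wild-type library 3, 0.128 without knock-in library 1 and 0.0710 without both libraries rich in haemoglobin. Its calls became 1 higher and 2 lower after length removal, 0 and 4 with quantile normalization, 1 and 7 after rescaling without erythroid and top genes and 2 and 5 with sample weights. They were 2 and 4 without knock-in library 1, 3 and 6 without both libraries rich in haemoglobin, and 0 and 0 with no filter or without wild-type library 2, 3 or knock-in library 2.

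The RhoA pathway list, which bears on the pathway in the series title, did not pass camera. It holds activators and effectors of the pathway together with inhibitors, so camera, which tests a shift in a common direction, can miss opposed changes. The values are mRNA levels, which do not measure the activity of the pathway. By mixed fry, which asks for change in either direction, the list passed (adjusted p = 0.000344), as did most lists (15 of 17 passed). Of 29 tested members, 2 fell and 1 rose, the same adjusted over the list alone, with a median log2 fold change of -0.04 (camera adjusted p = 0.858; adjusted p = 0.910 with an estimated correlation). Arhgap18 and Arhgap1, which encode GTPase-activating proteins, were the genes that fell, by 0.55 and 0.78 on the log2 scale. Ppp1cb, a myosin phosphatase subunit gene chosen after its values were seen, rose by 0.72. Rhoa itself, chosen after its values were seen, measured 125 ± 0.783 FPKM in the wild type and 110 ± 6.62 in the knock-in (SD, n = 3), which did not pass (log2 fold change -0.19, limma adjusted p = 0.269). The myosin light chain gene Myl6, the most abundant member, measured 10074 ± 261 and 12113 ± 883 FPKM (SD, n = 3; limma adjusted p = 0.0853). The calls of this list became 4 higher and 2 lower without knock-in library 1, 5 and 2 without both libraries rich in haemoglobin, 3 and 2 with sample weights and 2 and 2 with a robust variance estimate. They were 0 and 2 after rescaling without erythroid and top genes, 0 and 1 with no filter, 1 and 1 without wild-type library 1, and 0 and 0 without wild-type library 2, 3 or knock-in library 2.

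Of 29 genes of Rac and Cdc42 signalling and actin filaments, 7 fell and 2 rose, 11 and 2 adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.00774; adjusted p = 0.304 with an estimated correlation). The rises were those of Tmsb4x and of Dstn, an actin-depolymerizing factor gene chosen after its values were seen (log2 fold change 0.43). Wdr1, an actin disassembly factor, fell from 233 ± 5.59 to 147 ± 10.5 FPKM (SD, n = 3). Tmsb4x, which encodes the actin monomer binder thymosin β4, rose from 70178 ± 2622 to 113853 ± 13038 FPKM (SD, n = 3; limma adjusted p = 0.00969), and its log2 fold change of 0.69 became -0.38 with quantile normalization. It made up 9.99% to 11.2% of the total FPKM in wild-type and 11.6% to 15.8% in knock-in libraries. Without knock-in library 1 the list's camera adjusted p was 0.0580. The calls became 0 higher and 8 lower with quantile normalization, 1 and 8 after rescaling, 1 and 6 without wild-type library 1, 0 and 0 without wild-type library 2, 1 and 2 without wild-type library 3, and 0 and 2 with no filter or without knock-in library 2.

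Of 17 alpha granule genes, 2 fell and 0 rose, the same adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0263; adjusted p = 0.223 with an estimated correlation). They were Thbs1 and Selp, for P-selectin, which fell from 78.7 ± 9.42 to 40.9 ± 5.72 FPKM (SD, n = 3). The chemokine gene Pf4, the most abundant member, measured 18126 ± 897 FPKM in the wild type and 22247 ± 1692 in the knock-in (SD, n = 3), and did not pass (limma adjusted p = 0.0774). Its log2 fold change of 0.29 became -0.32 with quantile normalization. Of 18 dense granule and secretion genes, 4 fell and 0 rose, 5 and 0 adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.00290; adjusted p = 0.221 with an estimated correlation). Besides Rab32 they included Slc6a4, the serotonin transporter gene, which fell from 370 ± 15.2 to 251 ± 7.18 FPKM (SD, n = 3). The others, chosen after their values were seen, were the syntaxin gene Stx11 (log2 fold change -0.43) and the Rab27 effector gene Sytl4 (-0.52). The alpha granule call was lost with no filter (camera adjusted p = 0.165), without the variance trend (0.0581), without knock-in library 1 (0.128) and without both libraries rich in haemoglobin (0.126). The alpha granule calls became 2 higher and 2 lower without knock-in library 1 or without both libraries, 1 and 2 with sample weights or a robust variance estimate, and 0 and 1 without wild-type library 2 or knock-in library 2. The 4 dense granule falls became 0 without wild-type library 2, and 2 without wild-type library 3 or knock-in library 2, with 1 rise and 5 falls without both libraries.

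Of 25 G protein-coupled and cyclic nucleotide signalling genes, 5 fell and 0 rose, 7 and 2 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.00822; adjusted p = 0.223 with an estimated correlation). P2ry1, an ADP receptor gene, fell from 59.2 ± 2.84 to 31.5 ± 1.78 FPKM and the lipoxygenase gene Alox12 from 2933 ± 205 to 2151 ± 60.8 FPKM (SD, n = 3). The others, chosen after their values were seen, were the guanylate cyclase subunit gene Gucy1b3 (log2 fold change -0.55), the phosphodiesterase gene Pde5a (-0.67) and the thromboxane synthase gene Tbxas1 (-0.61). This list did not pass without knock-in library 1 (camera adjusted p = 0.0850) or without both libraries rich in haemoglobin (0.0813). Its calls became 0 higher and 2 lower after removal of the length trend, 1 and 6 at a mean FPKM of at least 5, 2 and 6 with sample weights, 1 and 5 with a robust variance estimate and 1 and 3 without wild-type library 1. They were 3 and 6 without knock-in library 1 or without both libraries, and 0 and 1 with no filter or without wild-type library 2, 3 or knock-in library 2. Gng11, a G protein subunit gene and the most abundant member, measured 7018 ± 294 and 8989 ± 990 FPKM (SD, n = 3; log2 fold change 0.35), which did not pass (limma adjusted p = 0.0629). It passed as higher at a mean FPKM of at least 5 (0.0445), with a robust variance estimate (0.0289), with sample weights (0.0206), without knock-in library 1 (0.00553) and without both libraries (0.000851). Of 25 ITAM and tyrosine kinase signalling genes, 6 fell and 1 rose, 9 and 1 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.00396; adjusted p = 0.221 with an estimated correlation). Prkcd, for protein kinase C delta, fell from 57.2 ± 4.97 to 26.2 ± 1.26 FPKM, and Orai1, for a store-operated calcium channel, from 37.0 ± 4.58 to 17.0 ± 1.43 FPKM (SD, n = 3). Fcer1g, the Fc receptor γ chain gene, was the member that rose, from 1368 ± 33.2 to 1868 ± 202 FPKM (SD, n = 3; limma adjusted p = 0.0271). The calls of this list became 0 higher and 6 lower with quantile normalization, 0 and 4 after length removal or without wild-type library 1, 0 and 2 with no filter or without wild-type library 3, 0 and 1 without wild-type library 2 and 0 and 3 without knock-in library 2.

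Of 16 apoptosis and life span genes, 2 fell and 0 rose, 4 and 1 adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.110). The sheddase gene Adam10 fell from 77.9 ± 7.27 to 52.5 ± 5.89 FPKM (SD, n = 3). The list passed at a mean FPKM of at least 5 (camera adjusted p = 0.0395) and by fry (adjusted p = 0.0345), and not with an estimated correlation (adjusted p = 0.266). The 2 falls became 0 without wild-type library 2, 1 with no filter, with quantile normalization, after length removal, or without wild-type library 3 or knock-in library 2, and 4 with sample weights or without both libraries rich in haemoglobin.

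Cytosolic ribosomal protein mRNAs rose together. Of 74 tested, 18 rose and 0 fell, 30 and 0 adjusted over the list alone, 69 had a positive log2 fold change, and the median was 0.58 (camera adjusted p = 3.24e-15; adjusted p = 0.0207 with an estimated correlation). It was the only 1 of the 17 lists to pass with an estimated correlation. Taken by symbol stem, among 62 stems, Rpl and Rps genes did not (adjusted p = 0.132 and adjusted p = 0.231 with an estimated correlation). Their summed level was 2089 ± 36.4 FPKM in the wild type and 3397 ± 229 in the knock-in (SD, n = 3). Rpl41, the most abundant, rose from 992 ± 32.9 to 1656 ± 187 FPKM and Rpl37 from 16.5 ± 0.609 to 35.8 ± 3.54 FPKM (SD, n = 3). Transcripts under 1000 nt had a median log2 fold change of 0.13 and those of 3000 to 5000 nt one of -0.12, and the median length of this list was 704 nt. The 18 rises became 7 with no filter, 3 without wild-type library 2, 9 without wild-type library 3, 7 without knock-in library 2 and 0 without knock-in library 3. Summed T and NK cell markers, given with the other cell types, were also higher in 3 of 3 knock-in libraries. Many ribosomal protein genes have processed pseudogenes, so single members are uncertain.

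Of 73 nuclear-encoded oxidative phosphorylation genes, 8 rose and 6 fell, 15 and 8 adjusted over the list alone, with a median of 0.00 (camera adjusted p = 0.426). These became 2 higher and 6 lower after removal of the length trend, 2 and 2 with no filter or without wild-type library 3, and 2 and 1 without wild-type library 2 or knock-in library 2. They were 12 and 10 without both libraries rich in haemoglobin, 12 and 5 without knock-in library 1 and 12 and 6 at a mean FPKM of at least 5. Cox7a2l, for a respiratory supercomplex factor, rose from 56.3 ± 2.96 to 119 ± 19.2 FPKM, and Ndufa4 from 648 ± 4.95 to 1037 ± 135 FPKM (SD, n = 3). Uqcrb, a complex III subunit gene, fell from 24.8 ± 0.690 to 10.5 ± 0.796 FPKM (SD, n = 3). In the unfolded protein response list 1 of 18 genes rose and 0 fell, the same adjusted over the list alone (median 0.23, camera adjusted p = 0.125). It was the stress transcription factor gene Atf4, which went from 65.2 ± 5.79 to 93.8 ± 4.52 FPKM, while Creld2 at 6.17 ± 0.560 and 2.60 ± 1.85 FPKM (SD, n = 3) did not pass (limma adjusted p = 0.0822). The list passed at a mean FPKM of at least 5 (camera adjusted p = 0.0457; adjusted p = 0.337 with an estimated correlation over all genes tested), and the Atf4 call was lost with no filter and without wild-type library 2, 3 or knock-in library 2. Its calls were 0 higher and 1 lower without knock-in library 2 and 2 and 0 without both libraries. In the interferon list 1 of 13 genes rose and 0 fell, the same adjusted over the list alone (median 0.14, camera adjusted p = 0.333). It was Ifitm3, at 321 ± 57.8 and 518 ± 74.8 FPKM (SD, n = 3; limma adjusted p = 0.0296), a call lost with no filter, with quantile normalization, after length removal and without wild-type library 1, 2 or knock-in library 2. The interferon calls were 1 higher and 1 lower at a mean FPKM of at least 5 or with sample weights, 1 and 2 without knock-in library 1 and 2 and 2 without both libraries.

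**Figure D2:**
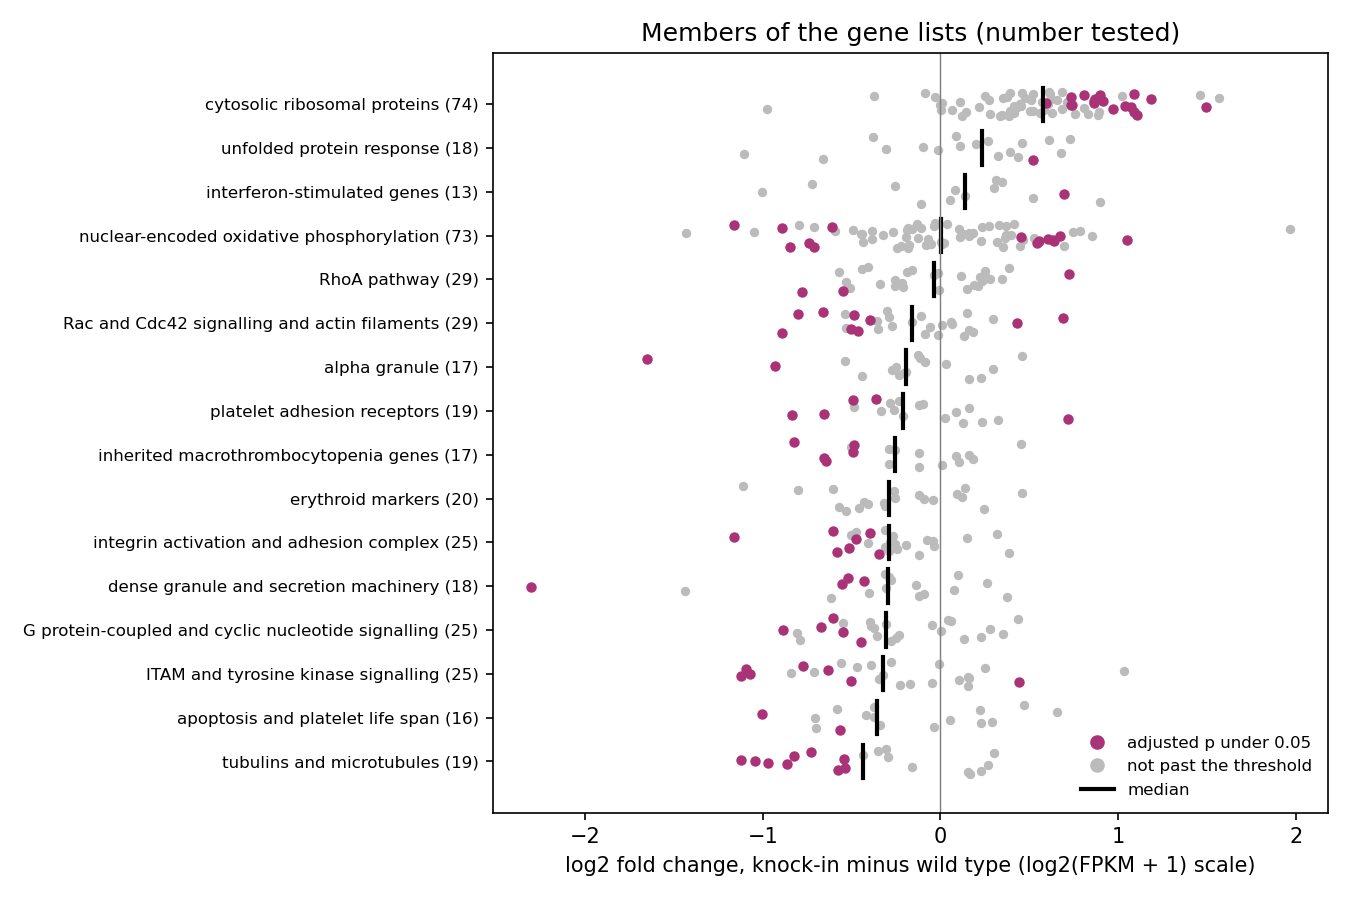
Log2 fold change, knock-in minus wild type on the log2(FPKM + 1) scale (horizontal axis), of each tested member of 16 lists (rows, with the number tested). Purple points passed an adjusted p of 0.05, grey points did not, and black bars are medians, from -0.43 for tubulins and microtubules to 0.58 for cytosolic ribosomal proteins.

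Markers of other cells differed between libraries. Haemoglobin mRNAs took 12.8%, 7.20% and 5.71% of total FPKM in wild-type libraries 1, 2 and 3, and 20.4%, 3.20% and 4.04% in knock-in libraries 1, 2 and 3. None of 20 erythroid markers passed, over all genes or adjusted over the list alone (median -0.29, camera adjusted p = 0.674), and Bnip3l, an autophagy receptor gene, measured 588 ± 102 and 697 ± 127 FPKM (SD, n = 3). Without wild-type library 1 and knock-in library 1, 13 erythroid markers fell, and 728 genes passed in all, with 22 ribosomal protein genes higher and 0 lower and 9 tubulin and microtubule genes lower and 1 higher. Without knock-in library 1 alone the erythroid list passed as lower (camera adjusted p = 3.46e-07). Neutrophil, monocyte, T and NK, B cell, cell division and immediate early lists had fewer than 5 tested members and no call over all genes. Summed T and NK cell markers were 6.80 to 8.68 FPKM in the wild type and 11.2 to 14.5 in the knock-in, higher in 3 of 3 knock-in libraries. Of these, Nkg7 (limma adjusted p = 0.151) and Cd28 (limma adjusted p = 0.163) passed adjusted over the list alone. Summed neutrophil markers were 62.5 to 69.1 against 63.2 to 73.6 FPKM, monocyte and macrophage markers 7037 to 8244 against 7206 to 9129, and B cell markers 17.5 to 22.1 against 11.4 to 20.3. The monocyte and macrophage sum was nearly all Lyz2. The B cell marker Cd37 (log2 fold change -0.60, limma adjusted p = 0.120) and the replication gene Pcna (-0.92, limma adjusted p = 0.0766) also passed adjusted over the list alone. Cell division genes summed to 38.2 to 65.8 FPKM in the wild type and to 138, 17.9 and 20.8 in knock-in libraries 1, 2 and 3, and immediate early and heat shock genes to 17.4 to 32.5 and 15.6 to 39.0.

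**Figure D3:**
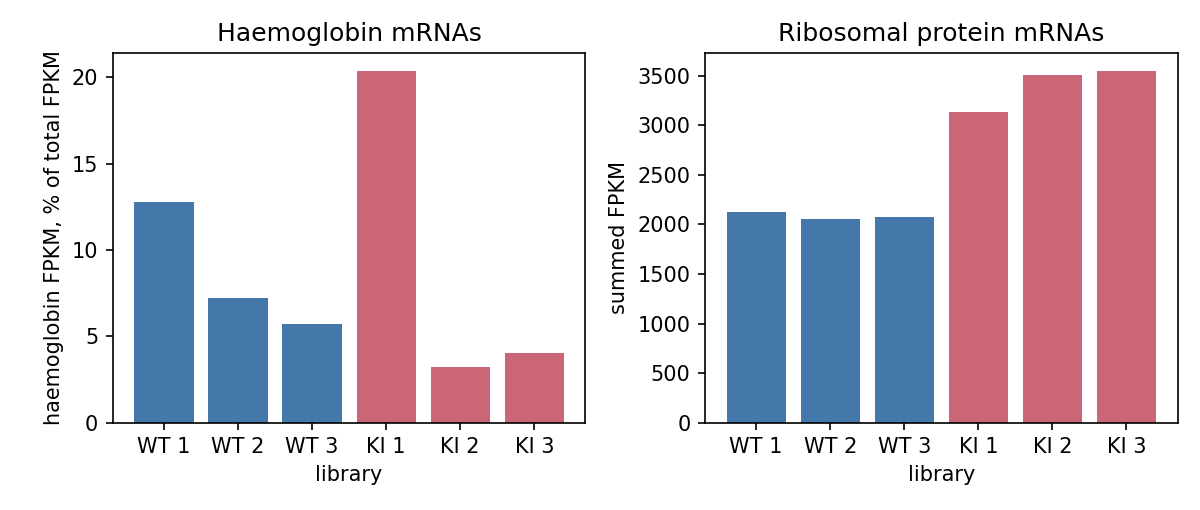
Haemoglobin mRNAs as a percent of total FPKM (left) and summed FPKM of cytosolic ribosomal protein mRNAs (right) in each library, with 1 bar per library. Haemoglobin is highest in knock-in library 1 at 20.4%, and the 3 knock-in libraries lie above the 3 wild-type libraries in the ribosomal protein sum.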

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

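The joint omission of the 2 libraries rich in haemoglobin and the length corrections were chosen after seeing the data. The count of 406 genes became 107 with no filter (49 higher, 58 lower; more genes are tested), 0 without the variance trend (0 and 0; 1197 at an unadjusted p under 0.05 in limma), 728 without both libraries rich in haemoglobin (362 and 366) and 179 with length trend and replicate block together (79 and 100). Sample weights gave 322 higher. Leaving out single libraries gave 0 to 610 genes, 0 to 307 higher and 0 to 303 lower. It was 0 without knock-in library 3, 41 without wild-type library 2, 113 without wild-type library 3, 85 without knock-in library 2 and 610 without knock-in library 1. Rescaling without erythroid and top genes gave 180 higher and 268 lower, beside 212 and 194. All 406 genes kept their direction where tested, except 2 of 406 with quantile normalization, where 404 did. Their values did not overlap between the groups. Omitted libraries, other pseudocounts, filters, weights or variance models therefore could not turn them, and only the other scalings and the length removal could.

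The count of 151 genes at least 2-fold apart became 381 with a pseudocount of 0.1, 32 with 5, 82 at a mean FPKM of at least 5, 352 without both libraries rich in haemoglobin and 159 to 297 without single libraries (245 without wild-type library 1, 297 without knock-in library 1). Of 17 lists, 10 passed camera with the preset correlation, 1 with an estimated correlation, 11 fry and 15 mixed fry, and 7 to 10 passed camera without single libraries. Itgb3 had -0.49 with no filter and with no trend and -0.38 after length removal with or without the block, none past the threshold, and -0.56 to -0.44 without single libraries.

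Results that reversed were not past the threshold where they did. Quantile normalization gave -0.38 for Tmsb4x, -0.32 for Pf4 and -0.10 for Lyz2. Plvap, not past the threshold in any setting, had -0.0139 after rescaling without erythroid and top genes and -0.0139 to 0.11 without single libraries. The RhoA list turned higher with no filter (adjusted p = 0.864), at a mean FPKM of at least 5 (0.680), without knock-in library 1 (0.798) and without both libraries rich in haemoglobin (0.752), within 0.607 to 0.955 without single libraries. The interferon list turned lower without knock-in library 1 (0.625) and without both (0.689), within 0.0928 to 0.633 without single libraries, and oxidative phosphorylation with length removal (0.286) and with the block added (0.225). Erythroid markers turned higher without wild-type library 1 (0.565), knock-in library 2 (0.204) or 3 (0.554), and were lower without knock-in library 1 (3.46e-07), all with the preset correlation. The estimated correlation of the erythroid list was 0.928 over all 6 libraries, so the preset overstates the evidence for it. Among other named genes, 1222 of the comparisons with an alternative kept direction and side of the threshold, 375 lost the call and 22 gained it; among lists 348 kept it, 27 lost it and 5 gained it. What caused these differences between settings was not tested.

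With the replicate number as a block 306 genes passed (166 higher, 140 lower), 287 of them shared with the 406, and Itgb3 stayed at -0.49 (adjusted p = 0.0342). The adhesion receptor list had a camera adjusted p of 0.0637 and did not pass; no other list's call differed. Atf4 (0.0571) and, among other named genes, Ly6c1, Arhgap1, Tgm2, Dstn, Pecam1, Stx11 and Pde5a did not pass either. The RhoA list had 1 gene higher and 1 lower, Rac and Cdc42 1 and 5, and oxidative phosphorylation 7 and 3. With length removal and the block, oxidative phosphorylation and Rac and Cdc42 each had 1 gene higher and 4 lower, RhoA 1 and 1, and ribosomal proteins 10 higher, histone genes 3. Lower were 5 of tubulins, 3 of macrothrombocytopenia, 3 of ITAM, 2 of integrin activation and 1 of dense granules, and the unfolded protein response had 0 calls. Deviations of same-numbered libraries correlated at 0.158, 0.0235 and 0.141, and those of other pairs at -0.160 to 0.0674. Knock-in library 2 correlated best with wild-type library 3 (0.0674), and the other differently numbered pairs were negative. Deviations were taken from the mean of each group, so positive values for some pairs force negative values for others. The negative values are therefore not separate evidence on pairing. The labels give no pairing, so the main test had group as the only term, but a pairing cannot be excluded. If the rough estimate of 7830000 to 9320000 fragments holds, genes near 1 FPKM rest on few fragments.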

Other observations

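The tests of symbol families, of erythroid cells and of abundant leukocyte mRNAs were chosen after the result was seen. Histone genes, a group outside the fixed lists, had higher FPKM in the knock-in libraries. They passed among 62 families of genes with a shared symbol stem, none of which passed with an estimated correlation. Of 23 tested histone genes, 9 rose and 0 fell, with a median log2 fold change of 0.55 (camera adjusted p = 4.46e-07; adjusted p = 0.349 with an estimated correlation). The median stayed positive under the 3 other scalings (0.56, 0.59 and 0.48), and the 9 rises became 5 with quantile normalization, 3 with no filter, 5 without wild-type library 1, 2 without wild-type library 2, 3 without wild-type library 3, 2 without knock-in library 2 and 0 without knock-in library 3, where no gene passed at all. Hist1h2bc, chosen after its values were seen, rose from 4056 ± 328 to 7022 ± 673 FPKM (SD, n = 3; limma adjusted p = 0.00759). Histone genes have near-identical copies, so single members are uncertain.

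The cytochrome c oxidase stem Cox had 5 of 17 genes higher and 0 lower, which were Cox7a2l and, chosen after their values were seen, Cox6b1, Cox6b2, Cox7a2 and Cox8a, with a median of 0.23 (camera adjusted p = 0.0225; adjusted p = 0.520 with an estimated correlation), and 1 higher after removal of the length trend, with no filter, or without wild-type library 2, 3 or knock-in library 2, and 0 without knock-in library 3. Other abundant mRNAs that rose, chosen after their values were seen, were Ctla2a from 14674 ± 958 to 28361 ± 3848 FPKM, the ferritin gene Fth1 from 20133 ± 1554 to 33061 ± 4816 and B2m, for the light chain of MHC class I, from 8604 ± 1059 to 13850 ± 1147 (SD, n = 3).

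The real grouping of the 6 libraries gave 406 genes, as 1 of 10 possible splits into 3 and 3, and the highest other split gave 2; 10 splits are too few for a share under 0.05.

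The rise of ribosomal protein mRNAs was set against 4 technical sources. Its median of 0.58 lay at percentile 100 of 10000 random lists matched on transcript length and expression (median 0.05, central 95% -0.08 to 0.20) and at percentile 100 of lists matched on GC content (-0.07, -0.19 to 0.05), which argues against either trend as the whole cause. Without both libraries rich in haemoglobin the median was 0.57, with erythroid markers at -0.89, which argues against erythroid cells. Abundant leukocyte mRNAs such as S100a8, S100a9 and Cd74 were 1.33 FPKM higher in sum, 0.102% of the ribosomal rise of 1309 FPKM, which argues against leukocytes that carry them. Lyz2, a monocyte marker not in that sum, stood at 7683 FPKM in the wild type and was 672 FPKM higher in the knock-in (51.4% of the ribosomal rise; wild-type SD 609, limma adjusted p = 0.575), and passed without both libraries rich in haemoglobin (log2 fold change 0.27, adjusted p = 0.0214). The mean log2 ratio of the 4 leukocyte lists was 0.12, with T and NK markers at 0.71 and B cell markers at -0.37. Each of these lists had 2 tested members. The monocyte sum was nearly all Lyz2 (7204.83 of 7205.81 FPKM in knock-in library 1). Most other monocyte markers were low, with a list median of 0.104 FPKM in the wild type and 0.0949 in the knock-in. These sums thus follow few genes and cannot decide on an admixture of other leukocytes. Among the hypotheses that remain, with no direct test here, is that ribosomal protein mRNA may make up a larger part of the mRNA of knock-in platelets. FPKM is relative to the library and does not measure the amount per platelet. Total FPKM was also higher in knock-in libraries (758381 to 856863 against 641278 to 708432), so the summed levels do not share the same total.

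Fabp4, Fabp5, Ly6c1 and Tgm2 rose, all genes that endothelial cells express, and Tgm2 was chosen after its values were seen (1.28 ± 0.279 to 4.30 ± 0.937 FPKM; SD, n = 3; limma adjusted p = 0.0235). Endothelial cells in the knock-in libraries could bring them. The sum of 9 other endothelial markers exceeded the highest wild-type library in 3 of 3 knock-in libraries, but by as little as 44.9 against 44.8 FPKM, within the wild-type SD of 3.91. Plvap, the most abundant of them, lay at 29.2 to 35.2 FPKM over the 6 libraries and made up most of the sum. The sum therefore mainly follows Plvap. Among the low markers, Cldn5 was higher and Kdr lower in 3 of 3 knock-in libraries. Endothelial cells and a change in platelets thus cannot be told apart here.

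A segment of donor chromosome around the edited Itgb3 locus could change neighbouring genes. Within 10 Mb of Itgb3, 8 of 96 tested genes passed (8.33%), against 393 of 4720 elsewhere (8.33%; one-sided Fisher exact p = 0.554). No excess was seen, but a few affected genes cannot be excluded at this number.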
